A study of Homo sapiens with 3 samples.

How the data were processed

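RNA of HaCaT cells, a spontaneously immortalized line of human epidermal keratinocytes, was measured on 3 single-colour NimbleGen expression arrays labelled with Cy3. According to the labels, the cells of the arrays were left untreated (control), given 1 µM all-trans retinoic acid (ATRA), or given ATRA together with nicotinamide (ATRA+NIC), for 36 h. The dose of nicotinamide is not given in the sources used here. Each group holds 1 array, and no array holds cells given nicotinamide alone.

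The deposited values of each array are intensities on a linear scale, summarised over 3 probes for each of 45033 transcripts, of which 2 had fewer probes. Per the file headers and labels these are RMA gene calls, a method that corrects background, normalizes across arrays and summarises probes. The software and its version are not given in the sources used here. The deposited intensities had nearly the same distribution on all 3 arrays, as quantile normalization leaves them, and were used without further scaling, as log2 values. A further deposited column, headed as a standard error of the expression value, held numbers of another kind whose unit the headers do not define, and it was not used. The series' value table, deposited by the authors, was checked against the array files: it holds the same intensities for the 31275 transcripts that reached 50 on all 3 arrays, and it served as an alternative.

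The file annotation gives a gene name for 42947 transcripts, while 2086 had none and were left out. Of 23619 Entrez gene numbers, 20230 matched a current symbol in a RefSeq table of the GRCh38.p14 assembly, which was used for names only, and the file's name was kept for the others. Coordinates are those of the files, on human build hg18. The level of a gene was the mean of the log2 values of its transcripts, which gave 23595 gene symbols. A gene entered the comparisons when its level was, on at least 1 array, at or above the median of all genes and arrays, a log2 level of 7.95 or an intensity of 246.5, and 12467 genes did so. Of these, 7074 had more than 1 transcript. RefSeq symbols for members of families with near-identical sequence, such as KRT6A, KRT6B and KRT6C or HSPA1A, are uncertain, since probes may bind more than 1 member.

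With 1 array per group no test between groups is possible, and no p-value is given. A difference was described by a fixed rule of size, at least 2-fold on the gene level. Where the dimmer side lay under an intensity of 50, the lowest value the authors keep in their value table, the fold was computed with every transcript value under 50 set to 50 and is written as "at least". The same holds where a transcript on the dimmer side lay under 50 and this moved the fold. LTF, ATP5MC3 and BIRC5, whose folds this took under 2-fold, are given with both folds instead. The step for single transcripts was added after the data had been seen, and counts and names follow the measured differences. The 2508 random probes on each array had intensities of 18.4 to 19.6. Lists of genes were fixed from knowledge of keratinocytes, retinoids and nicotinamide. There were 28 lists with 744 measured genes, and a gene could stand in more than 1 list. The median difference of the members passing the filter was placed among 10000 random lists of the same size matched on mean level in 20 bins. A list is said to stand apart when its percentile is under 2.5 or over 97.5, which 5% of lists of independently drawn genes do. Members of a list can vary together between any 2 cultures, so more lists may stand apart without an effect of treatment. This describes these arrays and is not a p-value. A list with fewer than 4 members passing the filter got values only. A further 8 lists were written after values had been seen and are used only in the closing observations.

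Named genes followed a rule. It took the 8 genes with the highest and the 8 with the lowest difference for ATRA against control and for ATRA+NIC against ATRA, among genes that passed the filter, carried a symbol other than a locus, clone or reading-frame name, and differed in the same direction in all transcripts. It also took the 3 members of each list with the greatest difference in each comparison, the members at least 2-fold changed in lists that are described, and a fixed set of retinoid, barrier, inflammatory and nicotinamide-related genes. The groups, comparisons, lists, naming rule and alternatives were set before the data were examined.

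The rule of size and the list percentile were tested on simulated arrays of 12467 genes, for ATRA against control. They were built from the real gene means over the 3 arrays, with a noise SD of 0.25 on the log2 scale per array. That SD came from the mean of the robust SDs, based on median deviations, of the 3 differences. ATRA against control had the largest of these, 0.39, so the simulated noise was smaller than the spread of that comparison. Of genes changed 2-fold, 45.5% of 66 were called, of those changed 3-fold, 98.5% of 66, and of those changed 4-fold, 100.0% of 68. Of 12267 unchanged genes, 0.383% were called, a rate that holds for this noise SD and rises with a wider spread, as given below. Of 200 unchanged lists of 20 genes, 3.5% stood apart, and a list of 20 genes shifted by 0.4 on the log2 scale lay at percentile 100.0. The noise was drawn for each gene separately, so members of these lists did not vary together.

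For the comparisons that share an array, unchanged arrays were simulated with normal noise. In the first version all arrays had the same spread, an SD of 0.35 taken from the mean variance of the 3 differences. In the second each array had the spread that the variances of the 3 differences imply, which fixes the covariance at the observed value by construction. Both spreads include any effect of treatment. For ATRA against control the first version gave 249 genes at least 2-fold higher and 265 lower, and the second 464 and 452. The alternatives tried were median centring, repeated quantile normalization, cyclic loess with 3 iterations, the series' value table, an offset of 100 before log2, no filter and stricter filters, other summaries of transcripts, thresholds of 1.5-fold and 3-fold, 10 bins or the control level for matching, and selection and measurement on different transcripts. Setting gene values, or transcript values, under 50 to 50 was added after the data had been seen. Their effect is given in the closing section. No scan or processing batch is recorded in the files. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 for cyclic loess, were used.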

Results

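Gene expression was measured in HaCaT keratinocytes left untreated, treated with all-trans retinoic acid (ATRA, the active metabolite of vitamin A), or treated with ATRA and nicotinamide (NIC, the amide form of vitamin B3), with 1 array per group. The series' title places the study in the field of epidermal barrier function. The median transcript intensity was 301.5 on the control array, 302.3 on the ATRA array and 297.9 on the ATRA+NIC array, and the highest values were 55677, 52595 and 55075. Random probes, which match no human transcript, lay at 18.9, 18.4 and 19.6. Between 73.6% and 73.8% of transcripts reached an intensity of 50. Across transcripts the correlation of log2 values was 0.978 between ATRA and control, 0.978 between ATRA+NIC and ATRA, and 0.985 between ATRA+NIC and control. There were no replicates, so the number of arrays limits the precision, no difference below has an error between cultures, and all are descriptions of these arrays. The only measure of scatter was technical. The differences of transcripts of the same gene had a pooled SD of 0.31, 0.30 and 0.24 on the log2 scale in these 3 comparisons.

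The comparison of ATRA with the untreated control asks which genes differ in keratinocytes exposed to the retinoid. CYP26A1 and CYP26B1, which encode enzymes that degrade retinoic acid and are classical retinoid-response genes, were 4.42-fold and 4.29-fold higher on the ATRA array. DHRS9, a retinol dehydrogenase, was at least 8.68-fold higher. Beside them stood genes of the immediate early response, of inflammation and of cell stress, with FOS at 20.7-fold, GDF15 at 19.5-fold, HMOX1 at 18.2-fold and HBEGF at 14.8-fold higher. Lower on the ATRA array were the basal keratin gene KRT5, by 2.96-fold, the cornified envelope precursor gene IVL, by 2.28-fold, and the proliferation marker MKI67, by 2.20-fold. Of 12467 genes, 477 were at least 2-fold higher and 257 at least 2-fold lower. Unchanged arrays with an SD of 0.35 per array, which includes any effect of treatment, gave 249 and 265, so the lower genes did not exceed that number. With the spread of each array that the 3 differences imply, which also includes any effect, unchanged arrays gave 464 and 452. The number of higher genes was close to that, so the counts alone do not separate effect from noise. Lower genes chosen on 1 transcript had a median of −1.20 there and −0.65 on a second transcript, where 85.0% of 180 were lower. Higher genes had medians of 1.33 and 1.25, and 97.1% of 310 were higher on the second.

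The 8 highest differences under the naming rule belonged to RASD1, which encodes a Ras-related GTPase (at least 8.20-fold), the neutrophil chemokine gene CXCL3 (at least 11-fold), FOS, the early-response transcription factor genes EGR3 (at least 14.3-fold) and EGR2 (at least 13.4-fold), GDF15, HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, and DHRS9. The 8 lowest by measured difference were IDO2 (at least 5.42-fold lower), APCDD1L (at least 5.63-fold), LALBA (5.28-fold), TNC, which encodes the matrix glycoprotein tenascin C (at least 3.19-fold), NPFF (5.14-fold), DYNLT4 (4.91-fold), the pseudogene GUSBP14 (4.73-fold) and CEND1 (4.42-fold). The naming rule left out locus, clone and reading-frame names. Other symbols made up 70.0% of the 257 lower genes, 96.9% of the 477 higher genes and 89.4% of all genes passing the filter. More than 1 transcript was present for 98 of the lower and 281 of the higher genes. In the hg18 annotation of the files, CYP26A1 lies on chromosome 10 at 94823656 to 94827631, DHRS9 on chromosome 2 at 169629544 to 169660923, FOS on chromosome 14 at 74815283 to 74818666, HMOX1 on chromosome 22 at 34107086 to 34120194 and HBEGF on chromosome 5 at 139692611 to 139706358.

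**Figure D1:**
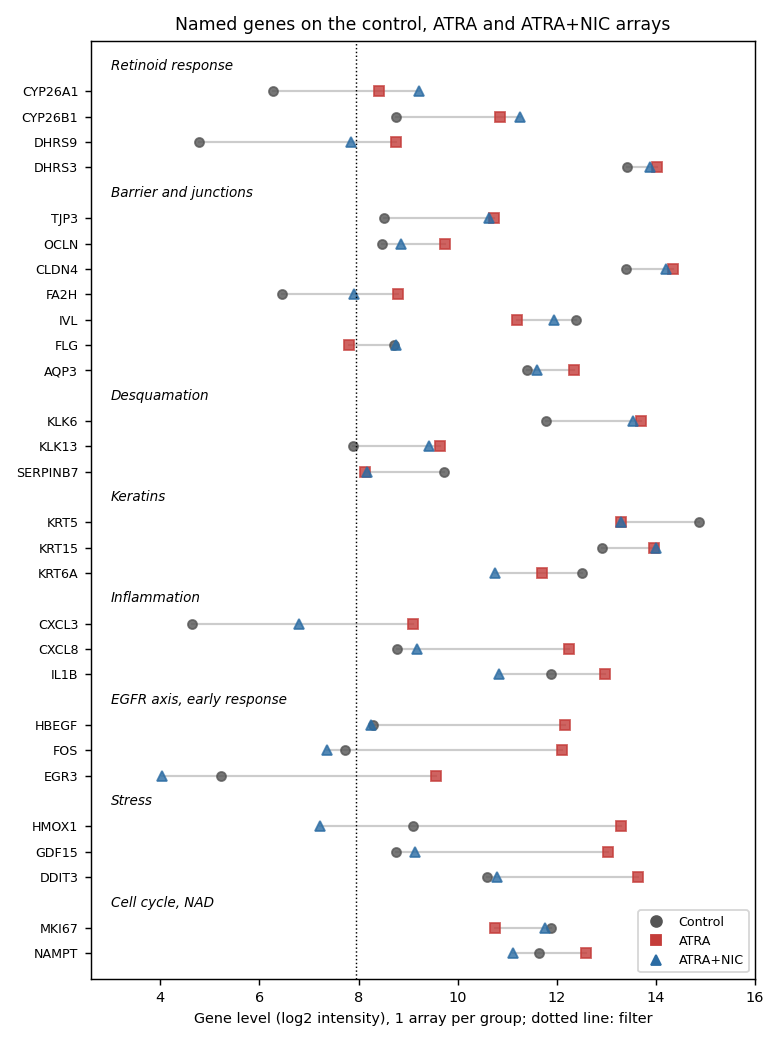
Gene level in log2 intensity (horizontal axis) of named genes on the control (circle), ATRA (square) and ATRA+NIC (triangle) arrays, 1 array per group, with a dotted line at the filter of 7.95. CYP26B1 and TJP3 lie higher on both treated arrays than on the control, while HBEGF, at 8.29, 12.17 and 8.25, is high on the ATRA array alone.

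Among the 19 genes of retinoid response and metabolism that passed the filter, 4 were at least 2-fold higher and 0 lower, and their median difference of 0.59 stood apart from random lists (percentile 100.0). These 4 were CYP26A1, CYP26B1, DHRS9 and ICAM1, an adhesion molecule gene at 3.40-fold. DHRS3, a retinaldehyde reductase gene, was 1.51-fold higher and CRABP2, which encodes a retinoic acid binding protein, 1.22-fold higher. RARB had log2 levels of 4.27, 4.56 and 4.49 on the control, ATRA and ATRA+NIC arrays, near background, and TGM2, at 6.23, 7.47 and 7.11, was also under the filter.

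Barrier genes went in both directions. In the cornified envelope list, 2 of 15 members were at least 2-fold higher and 1 lower, with a median of 0.16 (percentile 93.6). The higher ones were KLF4 (6.70-fold) and OVOL1 (6.66-fold), which encode transcription factors of epidermal differentiation, and the lower one was IVL. FLG, the filaggrin gene, had log2 levels of 8.72 and 7.81, a 1.88-fold difference, while TGM1 was at 9.02 and 9.03. The transcripts of KRT1 lay far apart and differed in sign, with the brighter at 12.47 and 12.33 and the dimmer at 3.84 and 4.61. LORICRIN (5.30, 5.52 and 5.27) and KRT10 (5.73, 6.06 and 6.54) were under the filter on all arrays. Of 17 tight junction genes, 3 were at least 2-fold higher and 0 lower, with a median of 0.07 (percentile 83.0). These were TJP3 (4.63-fold), which encodes a junctional scaffold protein, OCLN (2.40-fold), the occludin gene, and PARD6B (2.21-fold), a polarity gene. CLDN4 was 1.93-fold higher, and CLDN1 and TJP1 differed by −0.11 each on the log2 scale. None of 17 desmosome and adherens junction genes reached 2-fold, and their median was 0.06 (percentile 84.4). The largest differences there were 0.95 for NECTIN4, 0.92 for DSG3 and −0.75 for DSC3.

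Of 24 genes of the epidermal lipid barrier, 2 were at least 2-fold higher, FA2H (5.06-fold), which encodes a fatty acid hydroxylase of ceramide synthesis, and UGCG (2.06-fold), which makes glucosylceramide. The list median was 0.10 (percentile 94.5), and the serine palmitoyltransferase genes SPTLC1 and SPTLC2 differed by −0.06 and −0.01. The 24 cholesterol synthesis genes had a median of −0.04 (percentile 50.9), with SQLE, which encodes squalene epoxidase, at −0.81. Desquamation proteases and inhibitors stood apart with a median of 0.42 (percentile 100.0). Of 22 genes, 5 were at least 2-fold higher, the kallikrein protease genes KLK6 (3.79-fold), KLK13 (3.34-fold), KLK11 (2.44-fold) and KLK10 (2.11-fold) and the protease inhibitor gene SERPINB2 (2.17-fold). Another 2 were lower, SERPINB7 (3.01-fold) and KLK14 (2.08-fold), while KLK5 and KLK7 were 1.34-fold higher. In the water and hyaluronan list, 1 of 11 genes, the hyaluronan synthase gene HAS2, was 3.57-fold higher. The water channel gene AQP3 was 1.93-fold and HAS3, whose transcripts differed in sign, 1.51-fold higher, and the list median was 0.15 (percentile 92.9).

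Antimicrobial peptide genes stood apart (median 0.86, percentile 99.98), with 4 of 9 at least 2-fold higher. These were LCN2 (3.92-fold), which encodes the iron-siderophore binder lipocalin 2, ADM (2.93-fold), S100A9 (2.16-fold) and LTF, whose 2.01-fold was 1.65-fold with dim transcript values set to 50. Genes of basal keratinocytes and the basement membrane were lower as a list (median −0.32, percentile 0.030), with 3 of 22 at least 2-fold lower, KRT5, COL4A1 (2.28-fold) and COL7A1 (2.19-fold), and 1 higher, the basal keratin gene KRT15 (2.07-fold). The 6 wound and hyperproliferation keratins went both ways, with 3 higher and 3 lower. KRT17 was 2.02-fold and KRT16 1.99-fold higher, and the near-identical KRT6B and KRT6C had differences of −0.97 and −0.89. Their median was −0.37 (percentile 1.94). The 6 simple and mucosal keratins had a median of 0.28 (percentile 97.8) with none at 2-fold, KRT13 at 0.32, KRT18 at 0.37 and KRT4 at 0.61.

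Inflammatory mediators had the largest list median, 1.53 (percentile 100.0), with 13 of 23 at least 2-fold higher and 0 lower. Beside CXCL3, IL1RL1 (14.6-fold), which encodes a receptor for interleukin 33, CXCL8 (11.04-fold), PTGS2 (at least 5.46-fold), which encodes the inducible cyclooxygenase, CXCL2 (5.32-fold), IL1A (3.72-fold) and IL1B (2.12-fold) were higher. Genes of EGFR ligands, receptors and their early targets had a median of 1.46 (percentile 100.0), with 10 of 16 at least 2-fold higher and 0 lower. They included HBEGF, EREG (6.75-fold) and AREG (5.65-fold), which encode EGFR ligands, EGR1 (10.8-fold) and the feedback inhibitor genes SPRY4 (5.20-fold) and ERRFI1 (4.98-fold). In the unfolded protein and heat shock list, 13 of 23 genes were at least 2-fold higher and 0 lower (median 1.13, percentile 100.0). DDIT3 (8.21-fold), DNAJB9 (at least 6.39-fold), ATF3 (7.28-fold), TRIB3 (6.55-fold) and HERPUD1 (5.97-fold) led it, and the heat shock gene DNAJB1 was 3.17-fold higher. Of 22 p53 and apoptosis genes, 10 were at least 2-fold higher and 0 lower (median 0.63, percentile 100.0), with GADD45B at 6.58-fold and the cell cycle inhibitor gene CDKN1A at 3.28-fold. Metalloproteinase genes and their inhibitors had a median of 0.58 (percentile 100.0), with 6 of 16 higher, among them MMP7 (5.59-fold) and the urokinase gene PLAU (3.99-fold), and MMP2 lower (2.88-fold). Of 33 NRF2 and oxidative stress genes 7 were at least 2-fold higher, HMOX1, OSGIN1 (6.99-fold), TXNRD1 (2.45-fold), SRXN1 (2.23-fold), NFE2L2 (2.16-fold), SLC7A11 (2.04-fold) and GCLC (2.02-fold), with a list median of 0.12 (percentile 98.1).

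Cell cycle genes were lower together. Of 41 members 40 had a lower level on the ATRA array, with a median of −0.49 (percentile 0.000), although MKI67 was the only one at 2-fold, and BIRC5, a gene of the mitotic passenger complex, was just short of it. Respiratory chain genes were lower by a median of −0.20 (percentile 0.870), with ATP5MC3, which encodes a subunit of ATP synthase, 2.22-fold lower, or 1.38-fold with dim transcript values set to 50. Interferon-stimulated genes were higher by a median of 0.31 (percentile 100.0), with 1 of 40, the guanylate-binding protein gene GBP1, at 2.18-fold. Genes of NAD metabolism, sirtuins and PARPs had a median of 0.01 (percentile 71.7) and none reached 2-fold. NAMPT, the rate-limiting enzyme of NAD salvage from nicotinamide, differed by 0.96 and SIRT1 by 0.81, and NNMT, the nicotinamide methyltransferase gene, was under the filter at 5.53 and 5.36. Ribosomal protein genes (median 0.06, percentile 92.7) and reference genes (−0.08, percentile 29.5) did not stand apart, and none of their 45 and 26 members reached 2-fold.

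Markers of other cell types were mostly dim. Leukocyte markers that passed the filter, some only through their level on the ATRA array, had a median of 0.87 (percentile 99.8), and of all 14 measured 13 were higher on the ATRA array (median 0.86), with CD79A at 2.56-fold, CD3E at 1.00 and CD68 at 0.94 on the log2 scale. Only 1 melanocyte marker passed the filter, MITF, with a difference of 0.39, and 3 fibroblast markers did, TWIST1 at 0.35, COL1A1 at −0.12 and FBLN1 at −0.09. Among endothelial markers only CDH5, the gene of vascular endothelial cadherin, passed, and it was 12.1-fold higher on the ATRA array, in all 3 of its transcripts, while the other 10 endothelial markers had a median of −0.20.

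Of the 16 lists that stood apart in this comparison, 12 were high and 4 low, against 1.25 of 25 expected for independently drawn genes. Genes of a list that vary together between cultures would raise that number, which 1 array per group cannot show. The wound keratin list had a median of 0.03 without the filter (percentile 68.8) and the NRF2 list lay at percentile 84.97 with the brightest transcript of each gene, and that setting turned the water and hyaluronan median to −0.32. These calls depend on the processing, as do those of simple keratins and interferon genes at the 75th-percentile filter (percentiles 95.2 and 96.1). The number of lower genes was 130 with an offset of 100 before log2.

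**Figure D2:**
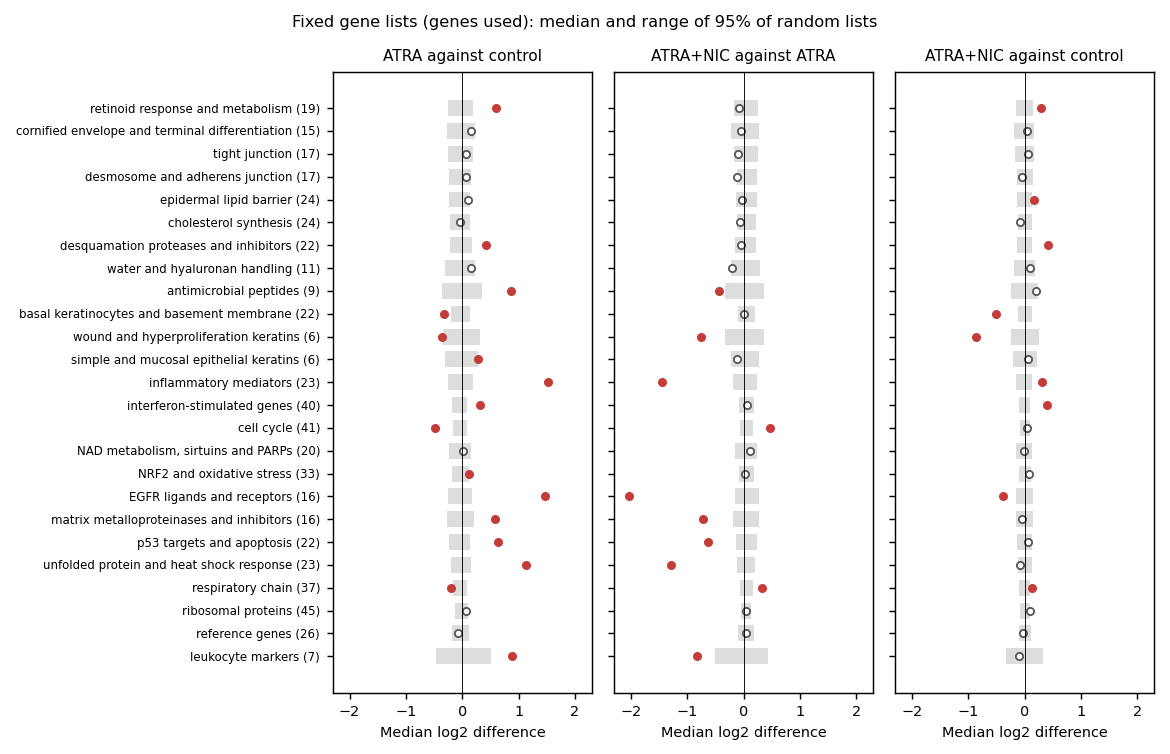
Median log2 difference of each fixed gene list (points, with the number of genes used in parentheses) in the 3 comparisons, and the range of 95% of random lists matched on level (grey bars). Filled points stand apart from random lists, such as inflammatory mediators at 1.53 for ATRA against control and −1.46 for ATRA+NIC against ATRA.

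The comparison of ATRA+NIC with ATRA asks which genes differ when nicotinamide is given with the retinoid. The genes that were high on the ATRA array were mostly lower on the ATRA+NIC array. This comparison shares the ATRA array with the previous one, so choosing genes high on that array builds in part of the fall. HMOX1 was 67.4-fold lower, FOS 26.4-fold, HBEGF 15.1-fold, CXCL8 8.31-fold and DDIT3, a transcription factor gene of the integrated stress response, 7.22-fold lower. Retinoid-response genes went both ways, with CYP26A1 at 0.80, CYP26B1 at 0.40 and DHRS9 at −0.91 on the log2 scale. MKI67 was 2.03-fold higher and PCNA, which encodes the sliding clamp of DNA replication, 2.46-fold higher. Of 12467 genes, 168 were at least 2-fold higher and 466 lower. Higher genes chosen on 1 transcript had a median of 1.17 there and 0.68 on a second transcript, where 89.2% of 102 were higher. Lower genes had medians of −1.36 and −1.18, and 96.1% of 304 were lower on the second.

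The 8 lowest were HMOX1, EGR3 (at least 15.2-fold), EGR2 (at least 13.4-fold), FOS, FOSB (21.9-fold), the heat shock gene HSPA6 (21.8-fold), the chemokine gene CCL4 (at least 9.61-fold) and NR4A1 (19.1-fold), an early-response nuclear receptor gene. The 8 highest were CFAP54 (at least 6.72-fold), the olfactory receptor gene OR13G1 (at least 11.1-fold), ARHGEF25 (4.90-fold), STPG3 (4.50-fold), NPY4R (4.24-fold), the cell cycle transcription factor gene E2F2 (4.20-fold), LALBA (4.03-fold) and FAM111B (3.81-fold). CFAP54 and OR13G1 were each read by a single transcript and lay under an intensity of 50 on both other arrays. Symbols other than locus, clone or reading-frame names made up 74.4% of the 168 higher genes and 95.3% of the 466 lower genes. More than 1 transcript was present for 62 of the higher and 278 of the lower genes.

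EGFR ligands and receptors had the lowest list median, −2.03 (percentile 0.000), with 11 of 16 genes at least 2-fold lower and 0 higher. ERRFI1 (11.05-fold), AREG (11.04-fold) and EGR1 (12.4-fold) were among them. Inflammatory mediators followed with −1.46 (percentile 0.000) and 14 of 23 lower, including IL1RL1 (at least 16.5-fold), PTGS2 (at least 6.30-fold), IL1A (9.61-fold) and IL1B (4.38-fold). The unfolded protein and heat shock list lay at −1.29 (percentile 0.000) with 12 of 23 lower, such as ATF3 (at least 9.66-fold), HERPUD1 (7.80-fold) and DNAJB9 (at least 7.34-fold). Metalloproteinase genes lay at −0.71 (5 of 16 lower, percentile 0.000), with MMP10 5.57-fold and PLAU 3.22-fold lower. Of the p53 and apoptosis genes, 10 of 22 were lower (median −0.63, percentile 0.000), including GADD45B (9.20-fold), PLK3 (6.24-fold), GADD45A (4.83-fold) and CDKN1A (4.39-fold). All 6 wound keratins were lower, none by 2-fold (median −0.76, percentile 0.010), with KRT6A at −0.95. All 9 antimicrobial peptide genes were lower (median −0.43, percentile 0.910), 3 of them at least 2-fold, ADM (3.46-fold), PI3 (2.08-fold) and S100A9 (2.04-fold), while LCN2 differed by −0.28. The 7 leukocyte markers that passed the filter, some only through the ATRA array, had a median of −0.82 (percentile 0.340), and 13 of all 14 measured were lower (median −0.88), with CD3E at 7.09-fold, CD79A at 2.75-fold and CD4 at 2.67-fold.

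Cell cycle genes were higher, 40 of 41 of them, with a median of 0.48 (percentile 100.0) and 4 at least 2-fold, PCNA, BIRC5 (2.10-fold, or 1.93-fold with dim transcript values set to 50), MKI67 and E2F1, at 1.00 on the log2 scale. Respiratory chain genes were also higher (33 of 37, median 0.33, percentile 100.0), with the complex I gene NDUFA2 at 2.03-fold and ATP5MC1 at 1.81-fold. The NAD list had a median of 0.12 (percentile 74.5). In it NAMPT was 2.80-fold lower, SIRT1 differed by −0.96 and NADK2 by 0.54.

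The other lists did not stand apart. The retinoid list lay at −0.08 (percentile 10.2), with BHLHE40 (2.78-fold) and ICAM1 (2.74-fold) lower. The cornified envelope list lay at −0.04 (percentile 23.4), with OVOL1 (4.19-fold) and KLF4 (4.06-fold) lower, FLG at 0.94 and IVL at 0.75. The tight junction list lay at −0.09 (percentile 9.90), with PARD6B 2.08-fold lower, OCLN at −0.88, CLDN1 at −0.65 and TJP3 at −0.09. The desmosome list lay at −0.11 (percentile 3.12), with DSG3 2.54-fold lower, and the lipid barrier list at −0.020 (percentile 20.0), with FA2H at −0.87, ABHD5 at −0.80 and SLC27A4 at 0.79. Cholesterol synthesis genes lay at −0.06 (percentile 8.74), and HMGCS1 (2.67-fold) and INSIG1 (2.22-fold) were lower. Desquamation genes lay at −0.05 (percentile 15.8), with SERPINB2 6.26-fold lower and KLK6 at −0.17. The water and hyaluronan list lay at −0.21 (percentile 2.73), with HAS2 3.21-fold lower, HAS3 at −0.80 and AQP3 at −0.74. Basal genes lay at 0.015 (percentile 30.3), with the epidermal master regulator gene TP63 2.70-fold lower. Simple keratins lay at −0.12 (percentile 10.9), with KRT13 at −0.40. The interferon list lay at 0.06 (percentile 54.6), with SAMD9L (2.37-fold) and IFIT3 (2.12-fold) higher. The NRF2 list lay at 0.03 (percentile 37.3), with 5 of 33 lower, HMOX1, OSGIN1 (4.78-fold), SLC7A11 (2.64-fold), SRXN1 (2.33-fold) and GCLC (2.11-fold). Ribosomal protein genes lay at 0.04 (percentile 54.1) and reference genes at 0.04 (percentile 46.9).

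Here 2 lists stood apart high and 8 low, against 1.25 of 25 expected for independently drawn genes. Each comparison shares an array with the others, so the list counts of the comparisons are not independent of one another. The number of higher genes was 75 with an offset of 100, and the water and hyaluronan list lay at percentile 0.230 with the median of transcripts, while melanocyte markers over all 12 measured members, nearly all under the filter, had a median of 0.48 (percentile 99.2).

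The comparison of ATRA+NIC with the untreated control asks what separates the doubly treated cells from untreated ones. Retinoid-response genes were higher, with CYP26A1 at 7.70-fold, CYP26B1 at 5.66-fold and DHRS9 at least 4.61-fold higher. CDH5 was 15.6-fold and TJP3 4.34-fold higher. Lower than in untreated cells were TNC, at least 4.36-fold, and the keratin genes KRT6B (3.67-fold) and KRT5 (2.97-fold). Of 12467 genes, 128 were at least 2-fold higher and 121 lower.

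The retinoid list stood apart (median 0.29, percentile 99.98), with 4 of 19 genes at least 2-fold higher, among them PLAAT4, a retinoid-inducible gene, at 2.55-fold. Desquamation genes did as well (median 0.41, percentile 100.0). KLK6 (3.37-fold), KLK13 (2.88-fold), KLK11 (2.65-fold) and KLK10 (2.22-fold) were higher, and PI3 (3.03-fold), SERPINB7 (2.92-fold) and SERPINB2 (2.88-fold) lower. Interferon-stimulated genes were higher in 35 of 40 cases (median 0.40, percentile 100.0), with SAMD9L at 2.78-fold and IFIT2 at 0.90 on the log2 scale. Inflammatory mediators had a median of 0.31 (percentile 100.0). In that list CXCL3 (at least 2.21-fold), CSF1 (2.19-fold) and PTGES (2.01-fold) were higher, and TNF (3.14-fold), IL1A (2.58-fold) and IL1B (2.07-fold) lower. The lipid barrier list had a median of 0.16 (percentile 99.2), with FA2H at 2.77-fold, and respiratory chain genes one of 0.12 (percentile 99.0), with none at 2-fold and NDUFB3 at 0.46.

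Lower as lists were the wound keratins (median −0.87, percentile 0.000), of which the near-identical KRT6A, KRT6B and KRT6C were at least 2-fold lower and the other 3, such as KRT16 at 0.61, higher, the basal genes (−0.51, percentile 0.000), with KRT5 2.97-fold lower and KRT15 2.12-fold higher, and the EGFR list (−0.39, percentile 0.000), with NRG1 (3.36-fold), an ERBB ligand gene, and ERRFI1 (2.22-fold) lower.

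The remaining lists did not stand apart. Medians were 0.03 for the cornified envelope (percentile 69.6), 0.06 for tight junctions (80.1), −0.06 for desmosomes (21.4), −0.09 for cholesterol synthesis (7.43), 0.09 for water and hyaluronan (83.5), 0.20 for antimicrobial peptides (94.6), 0.06 for simple keratins (67.5), 0.04 for the cell cycle (76.3), −0.02 for NAD metabolism (47.8), 0.07 for NRF2 (89.9), −0.05 for metalloproteinases (28.9), 0.05 for p53 targets (81.8), −0.08 for the unfolded protein and heat shock list (9.63), 0.09 for ribosomal proteins (96.6), −0.04 for reference genes (23.98) and −0.11 for leukocyte markers (31.0). Within them LCN2 was 3.23-fold, MMP7 3.50-fold, TIMP3 2.33-fold and BIRC3 2.06-fold higher, and MMP10 (3.10-fold), MMP2 (2.90-fold), MMP1 (2.17-fold), HMGCS1 (2.01-fold) and CD3E (3.55-fold) were lower. FLG lay at 8.72 on the control and 8.75 on the ATRA+NIC array, IVL at 12.38 and 11.94, OCLN at 8.48 and 8.86, AQP3 at 11.40 and 11.60, HBEGF at 8.29 and 8.25, and NAMPT at 11.63 and 11.11. Of 25 lists, 6 stood apart high and 3 low, against 1.25 expected for independently drawn genes. The lipid barrier list lay at percentile 88.4 without a filter, the inflammatory list at 95.4 and the wound keratins at 3.26, with a median of −0.23, so those calls depend on it. Melanocyte markers over all 12 measured members had a median of 0.46 (percentile 99.4), with MITF at 0.79.

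The 3 arrays together show how much of the difference from control was present on both treated arrays. Genes at least 2-fold higher on both numbered 78, CYP26A1, CYP26B1, DHRS9, TJP3, KLK6, LCN2 and CDH5 among them, and genes at least 2-fold lower on both 38, KRT5, TNC and MMP2 among them. Independent lists of these sizes would share 4.90 and 2.49 genes, and unchanged arrays of equal spread gave 46 and 45. That spread was taken from the observed differences and includes any effect of treatment. These numbers therefore do not say how many genes sharing the control array alone would give. Genes higher on ATRA than control and lower on ATRA+NIC than ATRA numbered 291, HMOX1, FOS and HBEGF among them, and genes with the opposite course 86. Independent lists would share 17.8 and 3.46, and unchanged arrays of equal spread gave 51 and 51. With the spread of each array taken from these same differences, the simulation gave 213 and 194 for these, 13 and 12 genes shared by both treated arrays and kept shares of 0.24 and 0.24 of the ATRA difference, but that spread includes any effect of treatment, so it does not separate noise from effect.

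Of the ATRA difference, genes at least 2-fold higher kept a median share of 0.14 on the ATRA+NIC array, and genes at least 2-fold lower a share of 0.37. Unchanged arrays of equal spread gave shares of 0.48 and 0.52. When genes were chosen on a transcript and measured on another of the same gene, the ratios of the summed differences were 0.17 for 310 higher genes and 0.42 for 180 lower genes. Across genes the correlation of both differences from control was 0.376 and their covariance 0.078, against 0.496 and 0.121 in unchanged arrays of equal spread. Genes are not independent replicates, and the shared control array alone gives a positive covariance, so these values do not show whether the treatments share an effect.

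**Figure D3:**
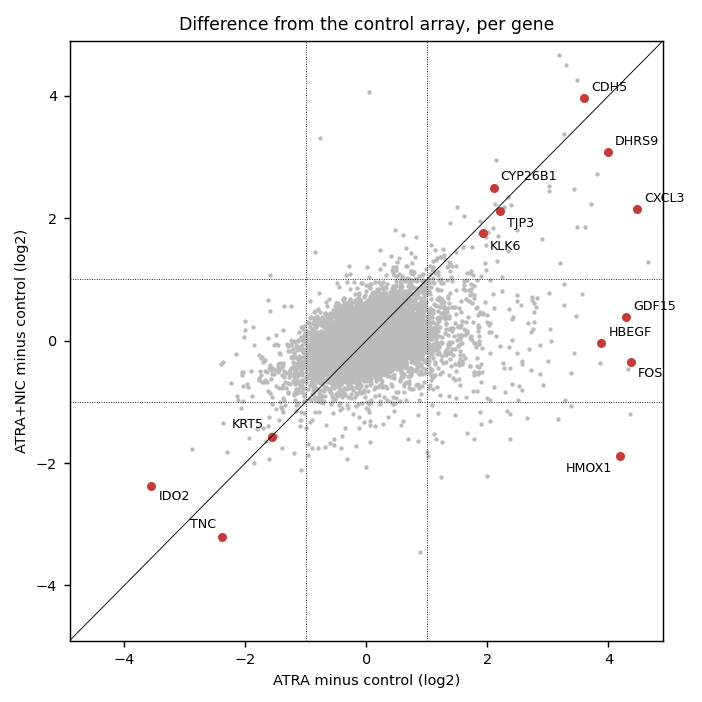
Log2 difference of each of 12467 genes from the control on the ATRA array (horizontal axis) and on the ATRA+NIC array (vertical axis), with dotted lines at 2-fold and a solid line of equal differences. CYP26B1, CDH5 and TJP3 lie near the solid line, while FOS, GDF15 and HBEGF lie near 0 on the vertical axis and HMOX1 below it, at −1.89.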

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

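The alternatives were chosen before the data were examined, except setting gene or transcript values under 50 to 50, which was chosen after. Of the counts of genes under an alternative, 62 stayed within 1.5 times the value reported and 28 moved. Of the list medians, 1013 kept their side of the limits, 19 newly stood apart, 13 no longer did and 2 reversed. Direction was checked only where a list stood apart in the reported setting or in the alternative. Of the medians of 25 lists in 3 comparisons, 57 were the same in all settings run and 18 changed in some. Of the values of 221 named genes, 7320 moved by less than the pooled SD between transcripts of a gene in that comparison. Another 282 moved by at least that much, and no difference of at least 2-fold changed sign. Of the 7320, 663 came from no filter, 573 from the filter on the mean level and 441 from the 75th-percentile filter. A change of filter cannot move the difference of a gene, so those values are no check. With gene values under 50 set to 50 the list medians did not move, and with transcript values set so no list call changed. Median centring and cyclic loess changed no list call. Except where its construction shows it, the cause was not tested. Counts follow from construction, as a lower threshold or no filter admits more genes and an offset shrinks the differences of dim ones. No paired analysis was possible because each group had 1 array. The files record no batches, so a comparison within batches gave no value. Signal over background limits dim genes, since random probes lay at 18.4 to 19.6.

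Counts of higher and lower genes are given for ATRA against control, ATRA+NIC against ATRA and ATRA+NIC against control. They were 1234 and 1121, 982 and 1181, and 494 and 483 at 1.5-fold, 193 and 58, 18 and 183, and 38 and 36 at 3-fold, 234 and 74, 48 and 221, and 44 and 48 at the 75th-percentile filter, and 997 and 759, 728 and 973, and 548 and 491 with no filter. With an offset of 100, 130 genes were lower for ATRA against control, 75 higher for ATRA+NIC against ATRA, and 74 higher and 69 lower for ATRA+NIC against control. The kept share of higher genes was 0.228 with no filter.

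For ATRA against control, the NRF2 list no longer stood apart at the 75th-percentile filter (median 0.026), with the brightest transcript (0.039) or with no filter (0.061), nor did interferon genes (0.11) and simple keratins (0.25) at the 75th-percentile filter. Wound keratins did not with the brightest transcript (−0.21), the filter on the mean level (−0.37) or matching in 10 bins (−0.37), and with no filter they reversed (0.029). The water and hyaluronan list reversed with the brightest transcript (−0.32). Ribosomal proteins newly stood apart when matched on the control level (0.058).

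For ATRA+NIC against ATRA, lists that newly stood apart were desmosomes matched on the control level (−0.11), interferon genes at the 75th-percentile filter (0.22), retinoid genes (−0.13) and simple keratins (−0.24) with no filter, and the water and hyaluronan list at the 75th-percentile filter (−0.38), with the median of transcripts (−0.37), with repeated quantile normalization (−0.21) and matched on the control level (−0.21).

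For ATRA+NIC against control, the lipid barrier list no longer stood apart at the 75th-percentile filter (0.11), with the median of transcripts (0.12) or with no filter (0.082), nor did inflammatory mediators (0.12) and wound keratins (−0.23) with no filter. Newly standing apart were cholesterol synthesis with no filter (−0.15) and in the series' value table (−0.14), desmosomes (−0.18) and tight junctions (0.17) with the brightest transcript, and ribosomal proteins with the brightest transcript (0.12), the median of transcripts (0.099), no filter (0.091), matching in 10 bins (0.091), matching on the control level (0.091) and the series' value table (0.091).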

Other observations

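Unless said otherwise, the tests in this part, and the lists for immediate early genes, endoplasmic reticulum stress, the amino acid response, heat shock factor targets and leukocyte classes, were chosen after the values had been seen. Of 30 measured immediate early genes, 28 passed the filter, with a median difference of 2.14 for ATRA against control (percentile 100.0), −2.35 for ATRA+NIC against ATRA (percentile 0.000) and −0.47 for ATRA+NIC against control (percentile 0.000). The 14 endoplasmic reticulum stress genes, chaperones and degradation factors such as HSPA5 and HERPUD1, had medians of 1.15, −1.15 and −0.11, with percentiles of 100.0, 0.000 and 10.0. The 15 amino acid response genes, such as DDIT3, TRIB3 and CHAC1, had medians of 1.03, −1.16 and −0.11, with percentiles of 100.0, 0.000 and 7.30. The 14 heat shock factor targets had medians of 0.69, −0.88 and −0.11, with percentiles of 100.0, 0.000 and 6.03. HSPA5, HERPUD1, DDIT3, TRIB3 and CHAC1 also stand in the fixed unfolded protein and heat shock list, whose values had been seen. The percentiles of these later lists therefore describe largely known differences and are no independent support. Their full overlap with the fixed lists is not counted here.

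Among genes at least 2-fold different from control on both treated arrays were several outside the fixed lists, named here after their values were seen. TRIM31, which encodes a ubiquitin ligase, had log2 levels of 9.94, 13.42 and 14.20 on the control, ATRA and ATRA+NIC arrays. PIGR, which encodes the receptor that carries antibodies across mucosal epithelia, lay at 6.43, 9.87 and 8.92, the cell-surface mucin gene MUC20 at 8.46, 10.80 and 10.80, MUC13 at 6.38, 8.36 and 7.53, the calcium-binding protein gene S100P at 5.66, 9.36 and 7.89, and the transcription factor genes FOXA1 at 9.57, 11.30 and 10.71 and FOXJ1 at 6.01, 8.13 and 8.24. On the low side, the matrix gene FN1 lay at 13.10, 11.61 and 11.54, THBS1 at 13.42, 12.34 and 11.31, the integrin gene ITGB6 at 10.89, 9.72 and 9.74, and OLFM4 at 12.15, 10.55 and 10.22.

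Early-response, stress and inflammatory genes were higher on the ATRA array than on both other arrays. Noise of single probe sets is argued against for genes with a second transcript, of any class. Of 310 such genes at least 2-fold higher on 1 transcript, 97.1% were also higher on the second. This does not cover CXCL3, HBEGF, CXCL8 and IL1B, each read by a single transcript. Whether transcripts of a gene share probes was not examined. Handling or culture state of the single ATRA sample could raise such genes, and the heat shock factor targets, with a median of 0.69, go with it, but 1 sample per group keeps it from being told apart from treatment. An exchange of the ATRA and ATRA+NIC labels also stays open, since retinoid genes were high on both arrays and their median differed by −0.080. An effect of ATRA that nicotinamide counters is a hypothesis the design names, and it was not tested beyond these values. Without an array of nicotinamide alone, it cannot be told apart from an effect of nicotinamide by itself. Against control, medians on the ATRA+NIC array were −0.47 for immediate early genes, −0.39 for the EGFR list and 0.31 for inflammatory mediators.

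Leukocyte genes were ordered from ATRA over control to ATRA+NIC, in 13 of 17 pan-leukocyte genes, 23 of 30 T and NK cell genes, 12 of 18 myeloid genes and 6 of 12 B cell genes, where 17.5%, 18.3%, 18.3% and 17.9% of equally bright genes had that order. Over all measured members the medians for ATRA against control, ATRA+NIC against ATRA and ATRA+NIC against control were 0.85, −1.60 and −0.42 in the pan-leukocyte list, 0.82, −0.99 and −0.43 in the T and NK list, 0.81, −0.94 and −0.25 in the myeloid list, and 0.63, −0.72 and −0.11 in the B cell list. A shift of all dim genes is argued against, because random lists of equally dim genes ranged from −0.32 to 0.30 for ATRA against control. Melanocyte, fibroblast and endothelial markers had medians of 0.05, −0.18 and −0.11. The 14 measured members of the fixed leukocyte list had a median of 0.86, above that range. The list had already stood apart on its members passing the filter, so this value largely repeats that result. RNA of leukocytes in the control and ATRA samples may contribute, and the 13 ordered genes go with it, but 5 of the 17 pan-leukocyte genes, 5 of the 30 T and NK genes, 3 of the 18 myeloid genes and 0 of the 12 B cell genes reached the filter in untreated HaCaT cells, and 3, 2, 3 and 3 also stand in the fixed list. Genes abundant in such cells did not settle it, with PTPRC at 5.07, 7.24 and 4.21, SRGN at 6.25, 6.97 and 5.83, CD52 at 6.40, 7.61 and 6.67 and LYZ at 6.87, 6.23 and 6.43 on the control, ATRA and ATRA+NIC arrays, and expression by the keratinocytes themselves stays open.

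CDH5, the gene of vascular endothelial cadherin on chromosome 16 at 64958063 to 64996190 in hg18, was higher on both treated arrays. Noise of a probe set is argued against, since all 3 transcripts differed, the smallest difference from control being 3.09 on the log2 scale. RNA of endothelial cells is argued against as well, because the other 10 endothelial markers had medians of −0.20 and 0.15 for ATRA and ATRA+NIC against control, although 2 and 1 of them were at least 2-fold higher at levels under the filter. Binding of another transcript by these probes was not examined, as probe sequences were not used here. A response of CDH5 to the retinoid in keratinocytes is a hypothesis consistent with these values and was not tested further.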
